A study of Mus musculus with 6 samples.

How the data were processed

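Heart RNA of 6 female mice was measured on Illumina bead arrays, with 1 array per mouse. The 3 control mice carried floxed Nelfb alleles, and the 3 knockout mice carried the same alleles with CreER, a Cre recombinase that tamoxifen activates. Per the labels, all were injected with tamoxifen at 8 weeks of age, ate regular chow, were fasted for 5 hours and were 20 weeks old at harvest. RNA was extracted with a column kit and amplified with biotin labelling, per the labels' protocols. The controls carried no CreER, so the effect of the recombinase itself and that of the deleted gene lie on the same side of the comparison. The labels name neither the promoter of CreER nor the deleted exons.

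The authors deposited 2 tables. The first holds intensity values that were not normalized, 1 per probe and array, with a detection p-value beside each, per the file headers. The second, the deposited value table, holds intensity values on a linear scale. Its 6 columns share 1 distribution of values, with a median of 97.5 or 97.6 in each. Its maximum of 29046.2 differs from the 27098.1 that quantile normalization of these 6 arrays gave, so how it was scaled is not given in the sources used here. The submitters' processing notes name GenomeStudio, with no version. Neither table is centred.

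The 2 tables name the groups in opposite ways. Each column of the table that was not normalized had the rank order of 1 column of the value table, with a Spearman rho of 1.00 over probes, where the highest rho of any other pair was 0.855. In all 6 cases the matching column carried the same replicate number and the other group name. The split of the arrays into 2 groups of 3 is therefore the same in both tables, and the sign of every difference depends on which names hold. Groups here follow the sample records, to which the value table is keyed, and arrays of the first table were assigned to records by this match of ranks over all probes. This choice was made after the tables were seen. With the headers of the first table every sign turns.

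The tables hold 25696 probes, of which 23977 had 1 gene symbol in the platform annotation used, 0 had several and 1719 are unnamed here. Of the symbols, 23961 equalled the current RefSeq symbol of the same gene identifier. The intensities that were not normalized were background-corrected and quantile-normalized with neqc of limma 3.58.1 in R 4.3.3, which infers the negative controls from the detection p-values, with an offset of 16. Probes with a detection p below 0.05 on at least 3 of the 6 arrays were kept, 10407 in all, of which 9827 had a gene symbol. The probe with the highest mean signal stood for its gene, which left 7579 genes. Of 1747 genes with several detected probes, 118 had at least 1 called probe, 21 of these had every probe called, and 0 had probes called in opposite directions. Genes were tested with limma (lmFit and eBayes, 2-sided) on the log2 scale, knockout against control, and called at a Benjamini-Hochberg adjusted p below 0.05. Errors of differences are limma's moderated standard errors (SE), and errors of group means are SDs over 3 arrays. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

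Before the data were examined, the tests, 37 gene lists, the alternative settings and the rule for naming genes were fixed. Lists with at least 3 tested genes were tested with camera of limma at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 35 lists tested. Beside it stand camera with an estimated correlation and fry, which asks whether the genes of a list move 1 way on balance and does not compare them with other genes. The naming rule took the NELF subunits, the 10 largest rises and 10 largest falls among called genes whose groups did not overlap (skipping placeholder symbols), and the members with the smallest p of each list. Up to 4 members were taken from lists that were called or held at least 3 called genes, and up to 2 from others. Genes outside the rule are marked as chosen after their values were seen.

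A gene not detected on any array of 1 group has only a bound there. Its fold is given as at least the bright group's mean over the dim group's mean, in which each dim value was raised to the lowest signal of a detected probe on that array. On 20 simulated data sets of 7579 genes with 200 seeded changes, the test of knockout against control recovered 28.8% of the genes changed by 0.5 on the log2 scale, 99.1% at 1, 99.4% at 1.5 and 100% at 2, and 5.2% of calls were false. The simulation used the shrunken variances of this fit and drew the noise of each gene and array independently. Variation shared between genes and an array that stands apart were therefore not simulated, and real recovery and error may be worse. The number of arrays limits the precision: an exact permutation test of 3 against 3 cannot give a p below 0.1.

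Alternatives covered the background correction, the deposited value table, median scaling, the offset, the detection filter, the probes per gene, the empirical Bayes settings, array weights, the replicate number as a block, the threshold, the list test and leaving out each array. The group names of the headers were added after seeing the data. Genome coordinates are not given, because the build of the array annotation is not given in the sources used here.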

Results

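The study asked how gene expression in the adult mouse heart differs after tamoxifen-induced recombination of floxed Nelfb, which encodes the B subunit of the negative elongation factor (NELF), a complex that holds RNA polymerase II in a paused state near promoters. RNA from 3 control and 3 knockout hearts was hybridised, 1 array per mouse. The mean signal per array before normalization was 228.2, 310.3 and 169.8 in the controls and 259.9, 247.3 and 208.0 in the knockouts. Between 38.8% and 43.8% of probes were detected per array. After normalization, Pearson's r over genes, which are not independent replicates, ran from 0.983 to 0.990 within groups and from 0.974 to 0.983 between them. The first principal component (44.8% of variance) separated the groups. On the second (18.2%) control array 1 stood apart, at 18.71 against -8.55 to 1.64 for the other 5 arrays. Without it 380 genes were called, 42.9% of them higher, against 52.8% with it.

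Nelfb signal was lower in all 3 knockout hearts than in any control heart. The probe with the higher signal fell from 7.06 ± 0.04 in controls to 5.44 ± 0.03 in knockouts (log2, SD, n = 3 each), a log2 difference of -1.61 ± 0.13 SE or 3.06-fold. The limma adjusted p was 0.000183. The other Nelfb probe was also lower, by 1.92-fold, with a log2 difference of -0.94 ± 0.14 SE. These signs, and every sign that follows, rest on the group names of the sample records. The headers of the table that was not normalized name the same arrays the other way round, and with them Nelfb is 1.61 higher in knockout on the log2 scale. Where the probes lie relative to the deleted exons is not known here. The genes of the other NELF subunits were not called: the log2 difference was -0.05 ± 0.17 SE for Nelfa, -0.17 ± 0.13 SE for Nelfcd and 0.14 ± 0.17 SE for Nelfe. The size of the Nelfb difference depends on the background correction: with none, the log2 difference was -0.80. In the authors' value table it was -1.0. The NELF list as a whole, with 4 genes tested, 1 called lower, and also 1 when adjusted over the list alone, was not called by camera (adjusted p = 0.137).

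**Figure D1:**
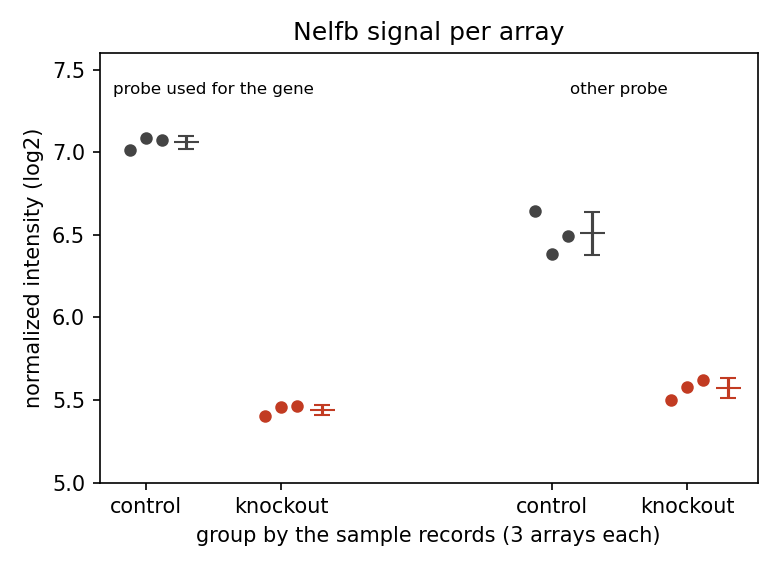
Normalized Nelfb intensity (log2, vertical axis) on each of the 3 control and 3 knockout arrays, grouped by the sample records, for both Nelfb probes. Points are arrays, and the bars beside them are mean and SD. On the probe used for the gene the controls average 7.06 and the knockouts 5.44.

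Skeletal alpha-actin (Acta1) rose most in the knockout hearts and the acyl-CoA thioesterase Acot1 was among the genes that fell most. Acta1 was 6.40-fold higher, a log2 difference of 2.68 ± 0.20 SE. It was followed by the histone gene H2ac18 (1.95 ± 0.18 SE), the histone gene H3c6 (1.68 ± 0.19 SE), the uridine-cytidine kinase Uck2 (1.64 ± 0.29 SE) and the Y-box protein gene Ybx2 (1.60 ± 0.18 SE). Lad1 (1.56), H4c11 (1.5), Trappc6a (1.5), the muscle adenylosuccinate synthase Adssl1 (1.49) and H2ac21 (1.44) completed the 10 largest rises. Acot1 was 4.91-fold lower, a log2 difference of -2.30 ± 0.29 SE. Close to it was Pdk4, a kinase that inhibits pyruvate dehydrogenase (-2.16 ± 0.50 SE), which fell further than Acot1 with no background correction (-1.88 against -1.63). Next came the fructose bisphosphatase Fbp2 (-2.13 ± 0.25 SE), the adenylate kinase Ak1 (-1.77 ± 0.21 SE) and Lgals4 (-1.70 ± 0.20 SE). The muscle phosphorylase kinase subunit Phkg1 (-1.64), Nelfb, the myosin light chain Myl1 (-1.58), Gstp2 (-1.56) and the phosphatase Ptpre (-1.53) were the other large falls. Acot1 and Gstp2 have close paralogs, whose transcripts their probes may also bind. All sizes and ranks in this paragraph are those of the main settings. They can change with the background correction, as for Nelfb, at -1.61 in the main fit and -0.80 with none.

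In all, 170 genes were higher and 152 lower in the knockout hearts among the 7579 tested (limma, Benjamini-Hochberg adjusted), or 4.25%. At least 2-fold changes were seen for 39 of the higher and 33 of the lower genes, and the median fold was 1.71 for the higher and 1.74 for the lower ones. All 322 had groups that did not overlap, as did 24.9% of all genes tested, where chance gives 10%. The count of 322 moved with the settings, from 54 with median scaling to 645 with a trended and robust variance prior. Leaving out 1 array gave 94 (without control replicate 3), 118 (without knockout replicate 2), 140 (without knockout replicate 3), 151 (without control replicate 2) or 208 genes (without knockout replicate 1), each over 1.5 times fewer. Among the genes with the largest changes, the call of Pdk4 was lost without control replicate 1, control replicate 3 or knockout replicate 3 (adjusted p = 0.0875, 0.150 and 0.0593), and that of Uck2 without control replicate 3 (adjusted p = 0.0514).

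Replication-dependent histone genes, which encode the core histones made in S phase, were higher as a group. Of the 30 tested, 19 rose and 1 fell, and 21 were higher and 5 lower when adjusted over the list alone. The members with the smallest p were H2ac18 (3.85-fold higher), H4c11 (2.82-fold), H3c6 (3.21-fold) and H3c4, with a log2 difference of 1.38 ± 0.15 SE. All 5 genes tested for H3 rose, as did 4 of 6 for H4 and 7 of 9 for H2B. The H2A genes went both ways: H2ac18, H2ac20 and H2ac21 rose, H2ac12 fell (-0.65 ± 0.15 SE), and the median of the 10 was -0.50. Genes within a class are near-identical, so their probes can bind transcripts of more than 1 of them and single genes are uncertain. With median scaling 9 histone genes were called higher, 0 of them for H2B, and the class medians kept their sign. The median log2 difference of the list was 0.90 (camera, adjusted p = 8.58e-13; adjusted p = 0.0844 with an estimated correlation). It was 0.54 with no background correction and 0.12 with no detection filter, which adds undetected genes to a list, and the list stayed called in both.

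**Figure D2:**
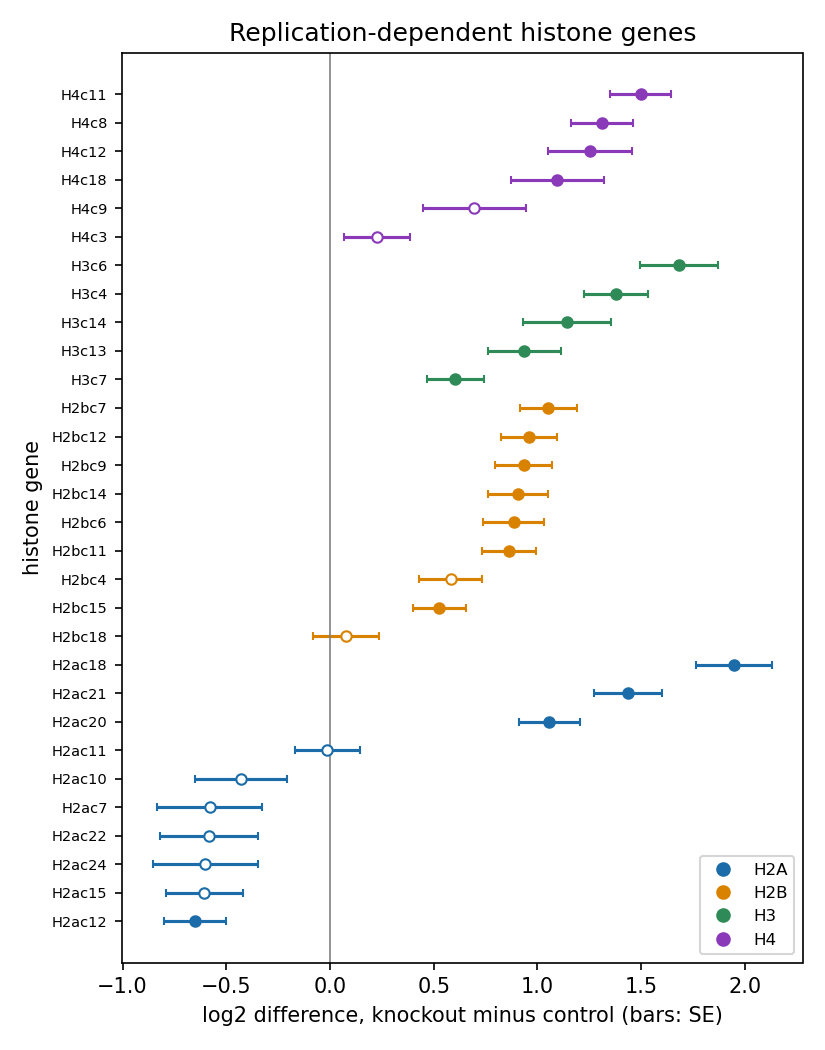
Log2 difference (knockout minus control, horizontal axis) of each of the 30 histone genes tested, coloured by class, with bars for the SE. Filled points are called and open points are not. H2B, H3 and H4 genes lie above 0, and H2A genes lie on both sides, by the group names of the sample records.

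Genes of mitochondrial energy metabolism were lower as groups. Of 23 genes of fatty acid uptake and beta-oxidation, 3 fell and none rose: Etfdh, which passes electrons from fatty acid oxidation to ubiquinone (-0.91 ± 0.17 SE), Cpt1b, the carnitine palmitoyltransferase of muscle mitochondria (-0.72 ± 0.17 SE), and the carnitine acetyltransferase Crat (-0.59 ± 0.15 SE). Adjusted over the list alone, 12 were lower. Acadl had a log2 difference of -0.56 and an adjusted p of 0.0517. The list's median was -0.40 (camera, adjusted p = 1.79e-06; adjusted p = 0.297 with an estimated correlation). Of 25 target genes of PPAR alpha, a nuclear receptor that drives fatty acid use, 5 fell and none rose: Acot1, Pdk4, Angptl4 (-1.28 ± 0.24 SE), the lipid droplet protein gene Plin5 (-1.12 ± 0.22 SE) and Cpt1b. Adjusted over the list alone, 11 were lower. The median was -0.40 (camera, adjusted p = 4.11e-06; adjusted p = 0.249 with an estimated correlation). It was -0.24 with no background correction and -0.23 with no detection filter, with the list still called. These 2 lists share 11 tested genes.

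The citric acid cycle and the respiratory chain lists were lower by camera with almost no single gene called. None of 21 genes of the citric acid cycle and pyruvate oxidation was called, 3 were lower when adjusted over the list alone, and the median was -0.32 (camera, adjusted p = 0.000801; adjusted p = 0.496 with an estimated correlation). Got1 (-0.70), Sdhc (-0.60), Idh3g (-0.48) and Pdha1 (-0.40) had the smallest p. None of 31 complex I genes was called, nor any when adjusted over the list alone, and the median was -0.17 (camera, adjusted p = 0.0246; adjusted p = 0.441 with an estimated correlation). Ndufb10 (-0.84), Ndufs3 (-0.39) and Ndufa2 (-0.37) were among the members with the smallest p, and Ndufb11, not detected on any knockout array, was at least 1.23-fold lower with an adjusted p of 0.0522. Of 38 genes of complexes II to V, Uqcrb fell (-0.84 ± 0.20 SE), 1 was higher and 4 were lower when adjusted over the list alone, and the median was -0.13 (camera, adjusted p = 0.0293; adjusted p = 0.489 with an estimated correlation). Cox7a1 (-0.51), Uqcrc1 (-0.54) and Atp5o (0.57) were not called. The list of complexes II to V shares 3 tested genes with the citric acid cycle list. Among them is Sdhc, which was lower in both when adjusted over each list alone. Both respiratory chain calls were lost with median scaling (adjusted p = 0.0760 for complex I and 0.219 for complexes II to V) and without control replicate 2 (0.101 and 0.0946), control replicate 3 (0.0824 and 0.0825) or knockout replicate 2 (0.0742 and 0.125). The complex I median was -0.10 without control replicate 2 and also without control replicate 3.

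**Figure D3:**
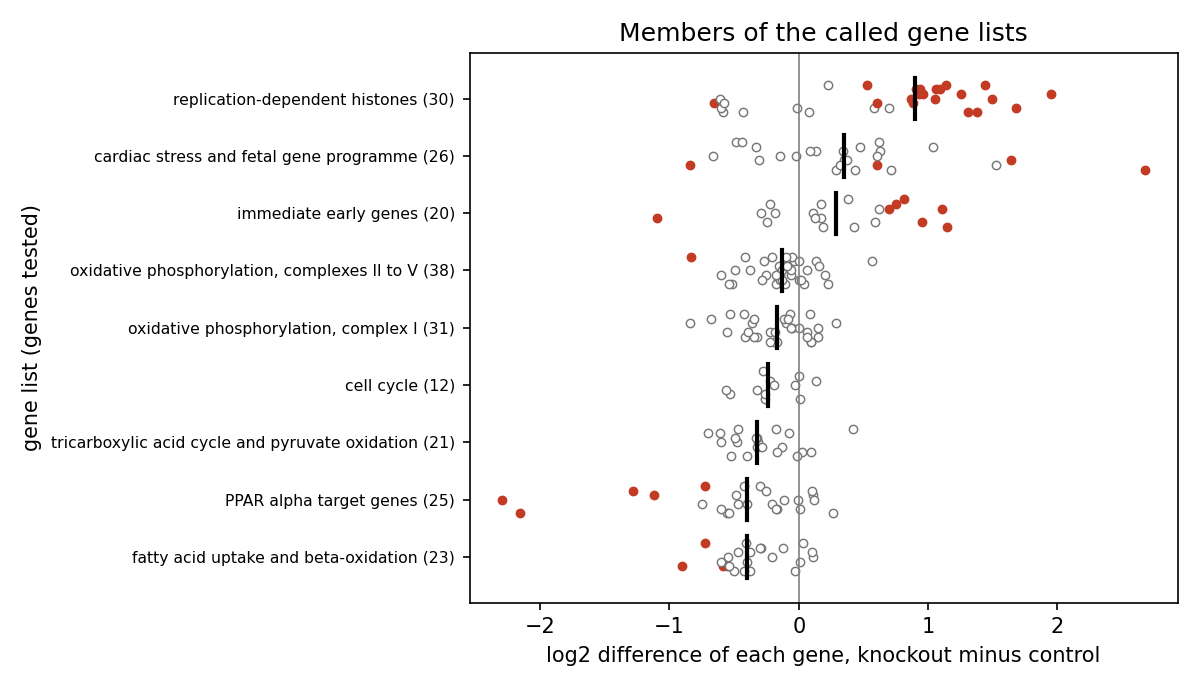
Log2 difference (knockout minus control, horizontal axis) of each gene in the 9 lists that camera called, with the number of genes tested in brackets. Filled points are called genes, open points are not, and black bars are medians, which run from -0.40 for the fatty acid and PPAR alpha lists to 0.90 for histones, by the group names of the sample records.

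Immediate early genes, which respond rapidly to stimuli, were higher as a group. Of 20 tested, 6 rose and 1 fell. Ccn1 (0.95 ± 0.13 SE), Junb (1.11 ± 0.18 SE) and Atf3 (1.15 ± 0.20 SE) rose, with Zfp36, Sgk1 and Fos, the last 3 named because they complete the count. Ier3 fell (-1.10 ± 0.18 SE). Adjusted over the list alone, 8 were higher and 1 lower. The median was 0.29 (camera, adjusted p = 0.00415; adjusted p = 0.399 with an estimated correlation). It was 0.18 with no background correction and 0.17 with no detection filter, with the list still called. Without control replicate 1, the array that stood apart, the adjusted p was 0.0761.

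The cardiac stress and fetal gene list was higher as a group, led by Acta1. Of 26 genes, Acta1, Uck2 and the desmin gene Des (0.60 ± 0.14 SE) rose, and the smooth muscle actin gene Acta2 fell (-0.84 ± 0.18 SE). Adjusted over the list alone, 7 were higher and 4 lower. The natriuretic peptide genes Nppa (0.37 ± 0.47 SE) and Nppb (0.60 ± 0.24 SE), chosen after their values were seen, were not called. Nppa was 14.24 on the log2 scale on knockout array 2 and between 11.71 and 12.81 on the other arrays. Myl4, also in this list and chosen after its values were seen, was not called (1.53 ± 0.88 SE). It was 10.23 on knockout array 1 and between 5.71 and 5.95 on the other arrays. The median of the list was 0.35 (camera, adjusted p = 0.0293; adjusted p = 0.691 with an estimated correlation), and the adjusted p was 0.0761 without control replicate 1 (median 0.40) and 0.175 without knockout replicate 2 (median 0.17).

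Cell cycle genes were lower as a group, with none of the 12 tested called and 1 lower when adjusted over the list alone. Of the 12, 6 had a mean signal less than 0.5 above the lowest detected signal, which averaged 4.62 on the log2 scale. The D-type cyclin genes Ccnd1 (-0.53) and Ccnd2 (-0.32), Prc1 (-0.57) and the replication licensing gene Mcm4 (-0.28) had the smallest p. The median was -0.24 (camera, adjusted p = 0.0463; adjusted p = 0.399 with an estimated correlation), and the call was lost under most of the other settings, as with no background correction (adjusted p = 0.0543), and without control replicate 1 (0.0761), control replicate 3 (0.0635), knockout replicate 1 (0.170) or knockout replicate 2 (0.0742). The median was -0.08 with no background correction, -0.12 in the authors' value table, -0.13 with an offset of 50, -0.04 with no detection filter and -0.16 without control replicate 3.

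Genes of cardiac ion channels and gap junctions held 4 falls and no rise among 19 tested. The pacemaker channel gene Hcn2 (-1.51 ± 0.19 SE) and the sodium channel subunit gene Scn4b (-0.92 ± 0.22 SE) fell. Gjc1, which encodes connexin 45, and Kcnip2, a potassium channel subunit gene, were not detected on any knockout array and were at least 1.44-fold and at least 1.32-fold lower. Adjusted over the list alone, 6 were lower. The list itself was not called (camera, adjusted p = 0.0650). The count of 4 fell to 2 with no background correction, to 1 with median scaling, and to 1 or 2 without any single array, and Hcn2 was the member called in each of these settings. Of 24 genes of the sarcomere and calcium handling, Ldb3 (0.91 ± 0.15 SE), Srl (0.81 ± 0.18 SE) and Asph (0.63 ± 0.14 SE) rose, Hrc had -0.65 and was not called, and the median was 0.04 (adjusted p = 0.447). Adjusted over the list alone, 4 were higher and 2 lower. Called sarcomere genes numbered 0 with median scaling, 6 in the authors' value table, and 1 without control replicate 3, knockout replicate 2 or knockout replicate 3.

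Other metabolic and regulatory lists were not called by camera, and single members changed in many of them. Among 14 genes of creatine kinase and energy transfer, the brain-type creatine kinase gene Ckb rose (1.18 ± 0.14 SE) and Ak1 fell (adjusted p = 0.837 for the list; 3 higher and 1 lower adjusted over the list alone). Among 21 genes of glycolysis and glucose uptake, Pfkfb2, whose product makes an activator of glycolysis, rose (1.01 ± 0.16 SE) and Pdk1 fell (-0.56 ± 0.14 SE), with an adjusted p of 0.287 for the list and 1 higher and 1 lower adjusted over the list alone. Pccb, a subunit of propionyl-CoA carboxylase, fell (-1.19 ± 0.18 SE) and Ppm1k had -0.65 among 17 genes of branched-chain amino acid and ketone catabolism (adjusted p = 0.202; 2 lower adjusted over the list alone). None of 20 transcriptional regulators of energy metabolism was called, Sirt1 at 0.38 and Tfb2m at -0.34 included (adjusted p = 0.447; 0 adjusted over the list alone). The clock genes Cry2 (-0.72 ± 0.15 SE) and Nr1d2 (-0.98 ± 0.22 SE) fell among 16 tested (adjusted p = 0.524; 1 higher and 2 lower adjusted over the list alone). None of 18 factors of polymerase pausing and elongation was called, with Paf1 at -0.61 and Ncbp1 at 0.41 (adjusted p = 0.837; 0 adjusted over the list alone).

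Single members of the stress-response lists changed, and none of these lists was called by camera. Cdkn1a, which encodes the cell cycle inhibitor p21, rose (1.27 ± 0.14 SE), as did Ddit4 (1.20 ± 0.26 SE), among 21 p53 target and DNA damage genes (camera, adjusted p = 0.290; 3 higher and 1 lower adjusted over the list alone). The amino acid transporter gene Slc7a5 rose (1.01 ± 0.15 SE) and Phgdh, not detected on any control array, was at least 1.33-fold higher among 23 genes of the integrated stress response (adjusted p = 0.447; 3 higher and 2 lower adjusted over the list alone). Dnajb1 rose (0.67 ± 0.14 SE) and Hspb1 had 0.69 without a call among 22 heat shock genes (adjusted p = 0.287; 4 higher and 1 lower adjusted over the list alone). Gpx3 rose (0.67 ± 0.16 SE) and Txnrd2 fell (-0.55 ± 0.13 SE) among 23 oxidative stress genes (adjusted p = 0.633; 3 higher and 4 lower adjusted over the list alone). Pink1, a kinase of mitochondrial quality control, fell (-0.95 ± 0.15 SE) and Casp9 had -0.39 among 25 genes of autophagy, apoptosis and atrophy (adjusted p = 0.683; 1 lower adjusted over the list alone). Nfkbia rose (0.57 ± 0.14 SE) and Osmr had 0.42 among 16 cytokine and adhesion genes (adjusted p = 0.912; 1 higher adjusted over the list alone). None of 27 interferon response genes was called, with Psmb9 at -0.56 and Bst2 at -0.55 (adjusted p = 0.253; 0 adjusted over the list alone).

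Markers of other cell types were not called as lists by camera. Among 16 fibroblast markers Gsn (1.13 ± 0.20 SE) and Mfap5 (0.83 ± 0.20 SE) rose, and the median was 0.09 (camera, adjusted p = 0.330; 2 higher adjusted over the list alone). Mfap5 was also the called gene among 25 of the extracellular matrix and fibrosis, where Ccn2 had 1.04 (adjusted p = 0.671; 2 higher adjusted over the list alone). Aqp1 rose (0.60 ± 0.15 SE) and Ramp2 had -0.38 among 21 endothelial markers (median -0.07, adjusted p = 0.767; 1 higher adjusted over the list alone). Acta2 fell and Higd1b had -0.56 among 16 smooth muscle and pericyte markers (median 0.03, adjusted p = 0.837; 2 lower adjusted over the list alone). Cd74 fell (-0.76 ± 0.17 SE) and H2-Aa had -0.64 among 21 macrophage and monocyte markers (median -0.17, adjusted p = 0.137; 1 lower adjusted over the list alone). Cidea fell (-0.65 ± 0.16 SE) and Scd1 had 0.51 among 7 adipocyte markers (adjusted p = 0.633; 1 higher and 1 lower adjusted over the list alone).

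Among 10 atrial markers Myl1 fell and Stard10 had -0.64 (camera, adjusted p = 0.948; 2 lower adjusted over the list alone). The camera direction of this list was down while its median was 0.12. The atrial light chain gene Myl4, chosen after its values were seen, was 10.23 on the log2 scale on knockout array 1 and between 5.71 and 5.95 on the other 5 arrays. No gene was called among 3 epicardial markers (Upk3b 0.57, Cldn15 0.44; adjusted p = 0.149; 2 higher adjusted over the list alone), 5 erythroid markers (Hba-a1 1.09 ± 0.57 SE, Alas2 0.90 ± 0.53 SE; adjusted p = 0.447; 0 adjusted over the list alone) or 3 lymphocyte and granulocyte markers (Cd247 0.28, S100a9 -0.26; adjusted p = 0.683; 0 adjusted over the list alone). Fast skeletal muscle markers (Myot 0.14, Tnni2 -0.12) and the female-specific Xist (0.04) gave lists too short to test, with 0 called. Xist averaged 4.79 in controls and 4.83 in knockouts on the log2 scale. This is near the lowest detected signal, which averaged 4.62, so Xist says little about the sex of the mice.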

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

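Nelfb kept its direction and call in every planned setting, between -0.80 with no background correction and -1.64 when single arrays were left out, and the 9 called lists kept their direction in every setting that left the sample records in place. Only the added use of the header group names, chosen after seeing the data, turned it (1.61). The count of changed genes (higher, lower) was 322 (170, 152). It was 563 (297, 266) with no background correction, 579 (288, 291) in the authors' value table, 558 (290, 268) with an offset of 50, 586 (286, 300) with array weights and 645 (321, 324) with a trended and robust prior. It was 54 (33, 21) with median scaling, 142 (81, 61) with no detection filter, where 16593 genes share the adjustment, and 81 (44, 37) at an adjusted p under 0.01. Except for the filter and the threshold, which act by construction, the cause was not tested. Of the 54, 50 were among the 322, and of the 563, 278. The strict filter gave 401, the 1.5-fold minimum 292, and testing every detected probe 336 genes with at least 1 called probe. Without 1 array the count ran from 94 to 380, higher genes from 52 to 163 and lower genes from 42 to 217, with 1 group at 2 arrays. Of 60 called named genes, 31 stayed called with median scaling and 32 with no filter, and 31 to 47 without 1 array. In all settings under the sample records in which the gene was tested, 23 stayed called and 0 turned. Of the uncalled named genes, 25 were called in at least 1 setting. The adjusted p under 0.01 and the 1.5-fold minimum were left out of these counts. No list was called with an estimated correlation (0 of 35), against 9 with the preset one and 5 (without knockout replicate 2) to 12 without 1 array. Of the 9, 4 were also called by fry, and the citric acid cycle (adjusted p = 0.108), complex I (0.0704), complexes II to V (0.116), cardiac stress (0.216) and cell cycle (0.0587) lists were not. The 3 other lists that fry called were NELF (0.00396), glycolysis (0.00396) and p53 targets (0.0485). Among uncalled genes the sign turned for Xist (-0.056 with median scaling, and -0.088 to 0.116 without 1 array), Nelfa (-0.220 to 0.048), S100a9 (-0.547 to 0.003), Myot (-0.088 to 0.319) and Tnni2 (-0.235 to 0.040). Samples with the same replicate number did not deviate together (correlations -0.05, 0.00 and -0.06), so expression gave no sign of a pairing by number. A pairing that leaves little shared signal cannot be excluded this way. With the replicate block 171 genes (92, 79) were called, and no list call changed. The slide as a block was not run, because the column names give no slide. Signal near background limits low genes: the lowest detected signal averaged 4.62 on the log2 scale.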

Other observations

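All tests in this part, the splits of the arrays included, were chosen after the results were seen. Directions follow the group names of the sample records.

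Cytosolic ribosomal protein genes were lower in the knockout hearts as a family. This family was 1 of 30 that were defined by symbol prefix and tested together after the data were seen. Other detected genes whose symbols start alike, such as those of S6 kinases (Rps6k), were not removed. Of 60 genes tested, 53 had a difference below 0 and 4 fell: Rpl36a (-0.96 ± 0.23 SE), Rpl5 (-0.89 ± 0.16 SE), Rps3a1 (-0.89 ± 0.20 SE) and Rpl39 (-0.65 ± 0.15 SE). The median was -0.23 (limma's camera, adjusted p = 4.71e-08 over the 30 families; adjusted p = 0.0889 with an estimated correlation), and it was between -0.25 and -0.20 under the 4 other scalings and offsets. The other 29 families were not called. Among them the 70 mitochondrial ribosomal protein genes had a median of 0.00, with 4 falls led by Mrps28 (-0.96 ± 0.15 SE). Glutathione S-transferase genes went both ways, with Gsto1 (0.85 ± 0.20 SE) and Gsto2 (0.67 ± 0.15 SE) higher and Gstp2, Gstm5 (-0.86 ± 0.19 SE) and Gstt1 (-0.79 ± 0.14 SE) lower. Of the vacuolar ATPase genes, Atp6v1g2 rose (1.38 ± 0.14 SE) and Atp6v0e2 fell (-1.0 ± 0.16 SE).

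Replication-independent histone variants rose in part. Of 6 tested, H2az1 (0.81 ± 0.16 SE) and H3f3b (0.73 ± 0.16 SE) rose, and H3f3a (0.35), Macroh2a1 (0.30), H2ax (0.12) and H2aj (-0.13) were not called by limma. Atrial and stress genes varied between the knockout hearts: Myl4 stood out on knockout array 1 (10.23), while Nppb (13.22, against 11.83 to 12.38 on the other arrays) and the beta myosin gene Myh7 (6.58, against 4.90 to 5.60) were highest on knockout array 2.

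The first pattern weighed is the opposite group names in the 2 tables. If the sample records had the names exchanged, Nelfb would be higher in their knockout arrays, but it was lower, by a log2 difference of -1.61 ± 0.13 SE. With the headers of the other table it was 1.61 higher in mice with the recombinase, which is what exchanged headers would give. That value is the same difference with its sign turned, and not a second test. The headers of that table are therefore the more likely error. This rests on 1 gene, measured by 2 probes whose place relative to the deleted exons is not known.

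The second pattern is the rise of histone genes. More cells in S phase would raise other genes of that phase alike. The mean log2 change of the histone list exceeded that of 6 cell cycle genes by 0.96 ± 0.04 SE over arrays. These 6 were kept for a mean signal at least 0.5 above the detection floor on the log2 scale, not for a role in S phase. They include the D-type cyclin genes Ccnd1 and Ccnd2. The mean change of the 6 was -0.31 ± 0.06 SE, and that of all 12 tested was -0.21 ± 0.05 SE. Only 12 of the 32 cell cycle genes on the array were tested. A gain of S-phase cells could therefore go unseen, and these values do not decide the question. Shared probe binding within a single class of paralogs would confine the rise to it, but called genes lay in 4 classes (3 with median scaling). Binding within each class stays open and could make several genes show 1 transcript. NELF takes part in the 3' end processing of these normally unpolyadenylated transcripts, so a rise of polyadenylated forms, if labelling read those better, may be involved, which no value here tests and which RNA measured with and without poly(A) selection would. It would not account for the rise of the variants H2az1 (0.81) and H3f3b (0.73), whose group of 6 had a mean change of 0.37 ± 0.09 SE over arrays.

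The third pattern is the fall of fatty acid oxidation genes. A lower share of cardiomyocytes would lower sarcomere genes too, but the fatty acid list's mean change lay below that of the sarcomere list by a difference of -0.41 ± 0.03 SE over arrays (-0.43 ± 0.06 SE with the 14 sarcomere genes of log2 signal under 13, away from saturation). A different time of day at harvest may contribute: clock genes in phase with Arntl and those in phase with Dbp moved apart by 0.51 ± 0.16 SE, and by 0.39 ± 0.15 SE without Nr1d2. Nr1d2 was the only gene of these 10 that was called, and a change of clock genes caused by the knockout would look the same. An effect of Nelfb loss itself stays open and untested.

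Of the 10 splits of the 6 arrays into 3 and 3, 1 gave as many changed genes as the real one (322), which is the real split itself, and the highest of the others gave 0. For called gene lists, 3 splits gave at least the real count of 9, and the highest of the others gave 11. The histone list had a camera adjusted p of 8.58e-13 in the real split. It was also called in other splits, at 0.000117, 0.000343, 0.000965 and 0.0394, and the remaining ones gave 0.0855 to 0.409. With 10 splits the share cannot fall under 0.05. Each of the other splits also mixes control and knockout arrays on both sides. Part of the real difference stays in such a split, and part adds to its spread within groups. The counts and the histone values of these splits are therefore no measure of chance.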
